A study of Mus musculus with 10 samples.

How the data were processed

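Gene expression was measured by Affymetrix whole-transcript arrays in colonic organoids, which are epithelial cultures grown from the stem cells of the colon. The organoids came from male mice on a C57BL/6J background, 3 per genotype. Knockout mice carried Pparg with exons 1 and 2 floxed and a Villin-Cre transgene, which directs recombination to the intestinal epithelium, and wild-type littermates served as controls. PPARγ is a nuclear receptor for fatty acids, and rosiglitazone is a drug that activates it. Organoids were treated for 24 h with 1 µM rosiglitazone or with 0.1% DMSO as vehicle, and 100 ng of total RNA with a RIN of at least 8.0 was labelled per array. The 10 arrays formed 4 groups. There were 3 knockout rosiglitazone arrays (replicates 1, 2 and 3 from mice 46, 45 and 44), 2 knockout vehicle arrays (mice 46 and 44), 3 wild-type rosiglitazone arrays (replicates 1, 2 and 3 from mice 48, 42 and 47) and 2 wild-type vehicle arrays (mice 42 and 47).

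The deposited table holds RMA expression on the log2 scale for 35556 probe sets in each of the 10 arrays, so the authors had corrected the background, quantile-normalized the arrays and summarised the probes of each probe set. The version of RMA and the chip definition were not given in the sources used here. All values lay between 0.73 and 13.55, array medians between 3.54 and 3.72, and 0 pairs of arrays were identical. All 10 columns were mapped to their samples by name. Arrays give no count depth, so the number of arrays limits the precision. The platform annotation table listed 23099 of the probe sets, and these were tested. The other 12457 were left out because no gene could be assigned, a restriction chosen after the data were seen. Of those tested, 21218 carried a single gene symbol and 1881 several, and 21185 of the single symbols matched a RefSeq gene of GRCm38.p6 by Entrez identifier. That assembly was used only for names and for which genes neighbour each other. There were 18820 distinct symbols, of which 1386 had several probe sets. For these the probe set with the highest mean over all 10 arrays stood for the gene.

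Differential expression was tested with limma 3.58.1 in R 4.3.3, using lmFit with a mean for each of the 4 groups over all 10 arrays, contrasts between groups, and eBayes. Tests were two-sided, adjusted by the Benjamini-Hochberg method over the 23099 probe sets, with a threshold of 0.05. The residual degrees of freedom were 6 and the prior degrees of freedom 4.39. There were 5 comparisons: rosiglitazone against vehicle in each genotype, the difference between these responses, and knockout against wild type under each treatment. Differences are given on the log2 scale with the standard error (SE) of the fit. Gene lists were tested with camera of limma, which compares the members of a list with all other genes, at a preset correlation between genes of 0.01, and adjusted over 32 lists. The adjusted p with a correlation estimated for each list stands beside each call. For the 13 lists called anywhere the estimate on all 10 arrays ran from 0.048 (PPAR targets) to 0.515 (glycolysis and hypoxia). The preset thus lay below the estimate for each of them, and p-values at the preset may be too small. The lists were written from textbook knowledge and covered PPAR targets and lipid metabolism, energy metabolism, intestinal cell types, cells outside the epithelium, defence and stress. They held 1135 entries, of which 1012 matched a tested gene. The way older symbols were matched was corrected after list results had been seen, since a looser rule (1017 matches) had assigned some symbols to other genes. The lists, comparisons, tests and most alternatives were fixed before the data were examined.

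Genes are named by a rule fixed in advance. It takes Pparg, up to 12 genes in each direction that passed the threshold with no overlap between the groups, the 10 genes with the smallest p where fewer than 10 passed, up to 4 members of each list that passed, and a few textbook PPAR targets. Predicted gene models are outside the rule, so 1810065E05Rik is named as a gene chosen after its values were seen.

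The mouse pairs the arrays of the 2 treatments, because the labels give each array its donor, and 4 of the 6 mice gave arrays of both treatments. In this pairing check the difference between wild-type mice 42 and 47 in vehicle correlated with that in rosiglitazone at r = 0.44 across probe sets, and that between knockout mice 44 and 46 at r = 0.487. Each of the 8 arrays of these mice correlated best with the other array of its own mouse. Replicate numbers in the titles do not mark the mouse, since 1 of the 4 numbers shared within a genotype stood for the same mouse. Fits with the donor as a random block (consensus correlation 0.438, statmod 1.5.0) or as a fixed block were alternatives to the fit without a block. Other alternatives were centring each array, repeated quantile normalization, only probe sets with a mean above the median, only the groups compared, an intensity trend, array weights, only mice with both treatments, and leaving out each array. None of these other alternatives held a block, so the arrays of a mouse counted as independent in them. All 35556 probe sets, lists on the mice with both treatments, looser symbol matching and a single mean per mouse were added after seeing the data.

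The fit without a block was tested on simulated data with 23099 probe sets, a mouse effect and this design. Each simulated comparison held 100 genes changed by 1 and 100 changed by 3 on the log2 scale together, beside a shifted list. Many large changes loosen the adjusted threshold, so the recovery at a change of 1 may be lower where few genes change. Of 100 genes changed by 1 on the log2 scale it recovered 58% for rosiglitazone in wild type, 66% for rosiglitazone in knockout, 25% for the difference of responses, 60% for genotype in vehicle and 66% for genotype in rosiglitazone. At a change of 3 it recovered 98%, 99%, 96%, 99% and 98%, with 0, 0, 0, 6 and 8 false calls. With the donor as a random block the recovery at a change of 1 was 80%, 82%, 48%, 66% and 64%, in the same order. False calls with the block were 5, 11, 9, 6 and 10. A shifted list was called in each of the 5 comparisons and 0 unshifted lists were, but the simulated genes were independent of each other. All members of the shifted list moved by the same amount, larger than the median of any list called here. The simulation thus cannot show whether shifts of the reported size would be found. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.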

Results

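Expression was compared across 10 arrays of mouse colonic organoids in a design of genotype and treatment, to ask which genes the PPARγ agonist rosiglitazone moved in the colonic epithelium and whether this needed PPARγ. The groups were wild-type vehicle (n = 2), wild-type rosiglitazone (n = 3), knockout vehicle (n = 2) and knockout rosiglitazone (n = 3). Arrays of a group correlated with each other at r from 0.986 to 0.991 in knockout rosiglitazone, 0.988 in knockout vehicle, 0.992 to 0.995 in wild-type rosiglitazone and 0.996 in wild-type vehicle. The first principal component held 27.4% of the variance and the second 17.7%. The first set apart the arrays of mouse 46, labelled knockout, at -31.75 in rosiglitazone and -39.3 in vehicle. The other arrays lay from -4.1 to 19.6.

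Pparg itself was measured by 1 probe set (10540897). In the arrays labelled knockout it read 8.58 and 8.47 in vehicle and 8.78, 7.37 and 8.41 in rosiglitazone replicates 1, 2 and 3. In wild-type arrays it read 8.34 and 8.41 in vehicle and 8.30, 7.59 and 7.93 in rosiglitazone. The difference between the arrays labelled knockout and wild type was 0.14 (SE 0.38, n = 2 and 2, adjusted p = 0.96) in vehicle and 0.25 (SE 0.31, n = 3 and 3, adjusted p = 0.999) in rosiglitazone. In vehicle it was -0.11 with the donor as a random block, and in rosiglitazone -0.05 without knockout-labelled rosiglitazone replicate 1. On the 4 mice with both treatments the difference in rosiglitazone was 0.84 (adjusted p = 0.256, from 0.256 to 1 over its alternatives). Only exons 1 and 2 were floxed and the place of the probes in the gene was not given in the sources used here, so this probe set checks neither the deletion nor the labels. Every direction between genotypes given here rests on the labels alone.

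In wild-type organoids, textbook PPAR target genes and genes of fatty acid oxidation were higher as groups after rosiglitazone at the preset correlation only (adjusted p = 0.804 and 0.855 with an estimated correlation), while no single gene passed. Acaa1b, a peroxisomal thiolase, differed by 1.22 (SE 0.37), Pdk4, the kinase that shuts down pyruvate dehydrogenase, by 0.97 (SE 0.43). Angptl4, a secreted inhibitor of lipoprotein lipase, differed by 1.08 (SE 0.74) and Cidec, a lipid droplet protein, by 1.00 (SE 0.47). Plin2, a coat protein of lipid droplets, differed by 0.45 (SE 0.23). All had n = 3 and 2 and, in the fit without a block, adjusted p = 1. With the donor as a fixed block the adjusted p was 0.257 for Pdk4 and Angptl4, 0.311 for Acaa1b and Cidec and 0.369 for Plin2. Within the paired mice the rosiglitazone arrays exceeded vehicle by 1.36 and 1.71 for Pdk4, 1.44 and 2.41 for Angptl4, 1.30 and 1.56 for Cidec, and 0.75 and 0.71 for Plin2 (mice 42 and 47). Wild-type rosiglitazone replicate 1, from mouse 48, which had no vehicle array, read 2.34 for Pdk4, 2.89 for Angptl4, 5.04 for Cidec and 7.97 for Plin2, against vehicle means of 2.50, 3.48, 4.89 and 8.07. Acaa1b exceeded vehicle by 1.23 and 1.89 in mice 42 and 47. In the array of mouse 48 Acaa1b also lay above the vehicle mean, though by less. Fabp1, Fabp4 and Cd36, carriers of fatty acids, were dim in all 4 groups (means 1.85 to 2.50) and differed by 0.12, -0.02 and -0.18. The Pdk4 vehicle mean lay in this dim range too, so its differences may be compressed.

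**Figure D1:**
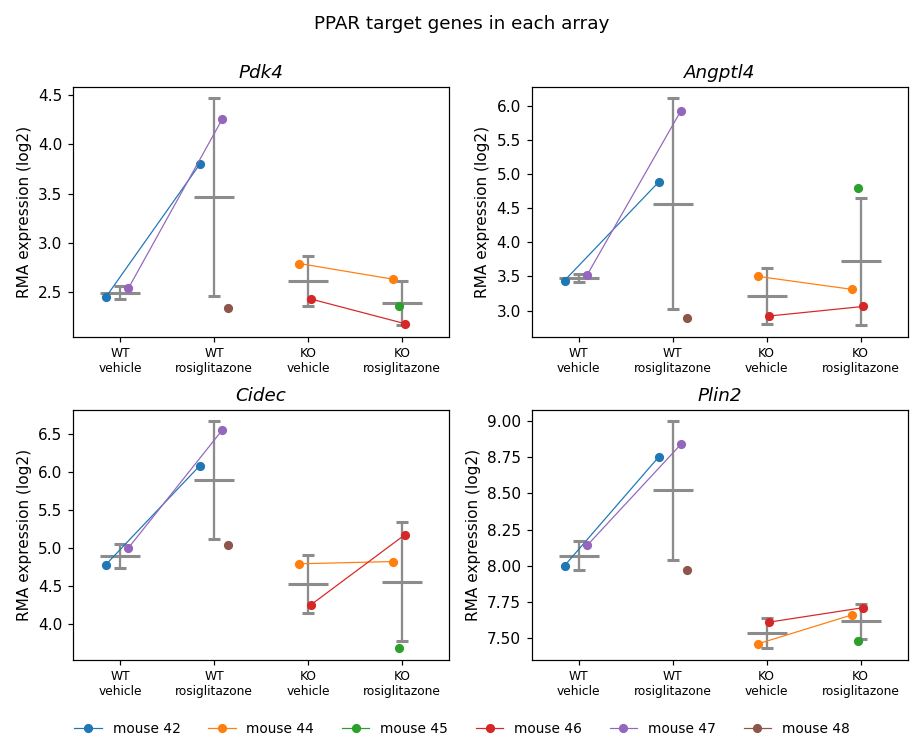
RMA expression (log2) of Pdk4, Angptl4, Cidec and Plin2 by group, with 1 point per array coloured by mouse, lines joining the arrays of a mouse, and grey bars for the group mean and SD. In wild type the arrays of mice 42 and 47 differ by 1.36 and 1.71 for Pdk4, whereas mouse 48 reads 2.34 beside a vehicle mean of 2.50.

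Among the 31 measured genes of fatty acid oxidation and ketogenesis, 27 were higher in wild-type rosiglitazone (median 0.10, adjusted p = 0.00409, camera; adjusted p = 0.855 with an estimated correlation). Of 46 textbook PPAR targets, 34 were higher (median 0.09, adjusted p = 0.0341; adjusted p = 0.804 with an estimated correlation). These lists share Acaa1b and Pdk4. The differentiated colonocyte list fell, with 33 of 41 genes lower (median -0.17, adjusted p = 0.000108; adjusted p = 0.804 with an estimated correlation). Its members included Slc9a3, the apical sodium-proton exchanger (-1.15, SE 0.49), Guca2a, the hormone guanylin (-1.02, SE 0.47), and Slc5a8, a transporter of short-chain fatty acids (-0.76, SE 0.35), against Fabp2 (0.48, SE 0.19). The interferon response list fell, with 33 of 41 genes lower (median -0.15, adjusted p = 0.00409; adjusted p = 0.855 with an estimated correlation), as with Oas1a (-0.48) and the immunoproteasome genes Psmb9 (-0.28) and Psmb8 (-0.52). Within mice 42 and 47 these differences were -0.26 and -0.17 for Oas1a, -0.24 and -0.07 for Psmb9, and 0.02 and -0.42 for Psmb8, smaller than with the array of mouse 48, and Slc9a3 came to -0.57 in these mice. Oxidative phosphorylation fell, with 31 of 46 genes lower (median -0.06, adjusted p = 0.00767; adjusted p = 0.855 with an estimated correlation), as with Atp5c1 (-0.37) and Ndufa4 (-0.22). Centring each array took its median to -0.02, while relative to the median of all probe sets it stayed at -0.08. With the donor as a random block its adjusted p was 0.227, while fatty acid synthesis passed (17 of 24 genes higher, median 0.12, adjusted p = 0.00868 with the block, 0.0847 without it; adjusted p = 0.72 with an estimated correlation and the block).

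Of 23099 probe sets, limma called 0 for rosiglitazone in wild type, with 229 at an unadjusted p under 0.05 where 1155 were expected by chance. With the donor as a random or a fixed block there were 697 and 889 (smallest adjusted p 0.719 and 0.257). The low number thus depended in part on leaving the mouse out of the fit. Adjusted over the list alone, 0 members of the 5 lists passed, with 2 of fatty acid oxidation, 3 of PPAR targets, 0 of oxidative phosphorylation, 2 of colonocyte and 0 of interferon genes at an unadjusted p under 0.05. In the fit without a block the 10 genes with the smallest p ran from -1.33 (Slc13a1, a sulfate transporter) to 0.86 (Zmynd12). They held Ppfia4 (0.58), Zfp980 (0.52), Vmn1r212 (0.47), L3mbtl1 (0.43), Mslnl (-0.43), Kbtbd13 (-0.56), Cfhr2 (-0.59) and Krt23 (-0.64). The lists of fatty acid oxidation and PPAR targets lost their calls without wild-type rosiglitazone replicate 2 (adjusted p = 0.163 for each), rosiglitazone replicate 3 (0.704 and 0.659) or vehicle replicate 1 (0.585 for each). PPAR targets also lost theirs without knockout-labelled rosiglitazone replicate 3 (0.0654) or either vehicle replicate of that genotype (0.0581 for each). The colonocyte, interferon and oxidative phosphorylation calls ended without wild-type rosiglitazone replicate 1 (0.211, 0.182 and 0.767, the last turning direction) or vehicle replicate 2 (0.0894, 0.182 and 0.24). The colonocyte and interferon calls also ended without rosiglitazone replicate 2 (0.0622 and 0.254). On the 4 mice with both treatments fatty acid oxidation had an adjusted p of 2.7e-14 and PPAR targets of 3.23e-09 (0.496 and 0.243 with an estimated correlation). Values that small rest on the preset correlation of 0.01, where the estimates on all 10 arrays were 0.35 and 0.048. On these mice the other 3 lists lost their calls, with colonocyte genes at 0.0798, interferon at 0.197 and oxidative phosphorylation at 0.721 with its direction turned (median 0.00), and lists passing numbered 7 higher and 0 lower against 2 and 3. Without wild-type rosiglitazone replicate 1 they numbered 5 higher and 0 lower.

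In the arrays labelled knockout, genes of goblet cells and of deep crypt secretory and Paneth cells were higher as groups after rosiglitazone at the preset correlation only (adjusted p = 0.909 each with an estimated correlation). The PPAR target list was not called (24 of 46 genes higher, median 0.00, adjusted p = 0.918). The differences for Pdk4, Angptl4, Cidec and Plin2 were -0.22 (SE 0.43), 0.51 (SE 0.74), 0.03 (SE 0.47) and 0.08 (SE 0.23), each with n = 3 and 2 and adjusted p = 1. Without rosiglitazone replicate 2, the array of mouse 45, they were -0.20, -0.03, 0.47 and 0.15, the Angptl4 reading of that array being 4.79 against 3.06 and 3.31 in the others of its group. Muc2, the gel-forming mucin of goblet cells, differed by 1.67 (SE 1.07), and Retnlb, a goblet cell peptide, by 1.53 (SE 0.97). Spink4, also of goblet cells, differed by 1.68 (SE 1.14), Reg4, a marker of deep crypt secretory cells, by 1.73 (SE 0.94), and Defa24, a Paneth cell defensin, by 2.02 (SE 1.06). Most of this lay in rosiglitazone replicate 2, from mouse 45, which had no vehicle array and read 8.47 for Muc2, 8.77 for Spink4, 7.10 for Reg4 and 7.05 for Defa24. The other arrays labelled knockout read 3.71 to 6.59 for Muc2 and 1.94 to 3.45 for Defa24, and without that array the differences were 0.60 for Muc2, 0.19 for Retnlb, 0.66 for Reg4 and 0.57 for Defa24. Mice 46 and 44 then went opposite ways for Reg4 (-0.55 and 1.87), Defa24 (-0.21 and 1.35) and Spink4 (-0.24 and 0.95).

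**Figure D2:**
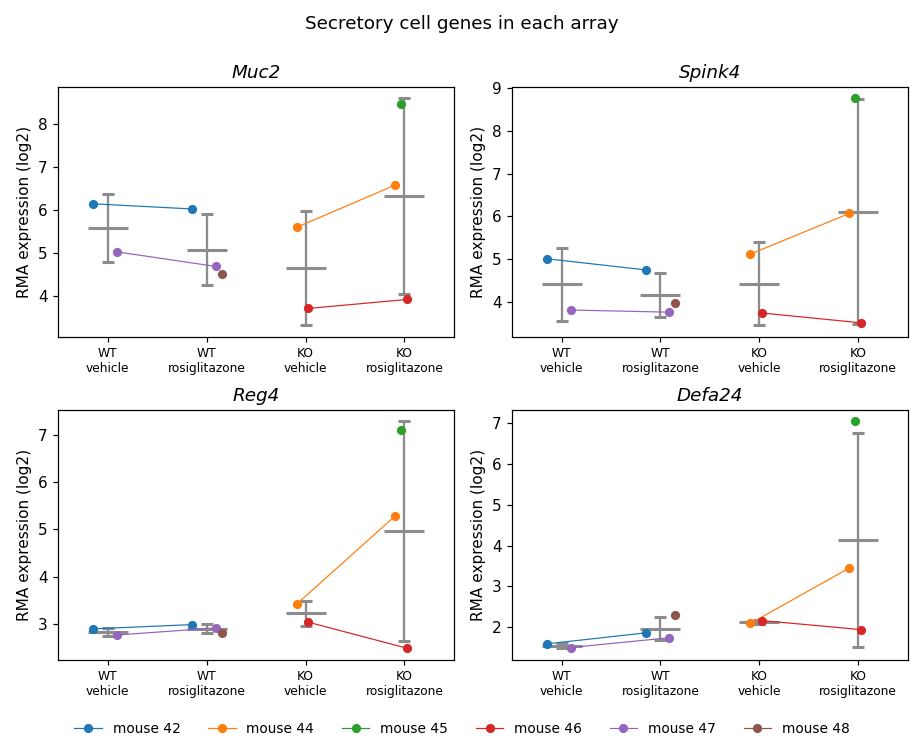
RMA expression (log2) of Muc2, Spink4, Reg4 and Defa24 by group, with 1 point per array coloured by mouse, lines joining the arrays of a mouse, and grey bars for the group mean and SD. The array of mouse 45 reads 8.47 for Muc2 and 7.05 for Defa24, the highest of the 10 arrays in each.

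The goblet cell list was higher in 19 of 27 genes (median 0.14, adjusted p = 0.0432), although Tff1 differed by -0.47, and the deep crypt secretory and Paneth cell list in 12 of 15 (median 0.19, adjusted p = 0.00729). Proliferation genes were higher in 30 of 42 (median 0.08, adjusted p = 0.00648), as with Mcm3, a subunit of the replicative helicase (0.41), and Mybl2 (0.38). Fatty acid oxidation was higher in 21 of 31 (median 0.10, adjusted p = 0.0432), with Cpt1a, the gate of fatty acid entry into mitochondria, at 0.29 and Hadha at 0.31. Oxidative phosphorylation was higher in 33 of 46 (median 0.05, adjusted p = 0.0432), with Ndufa4 at 0.44. Glycolysis and hypoxia genes fell, with 28 of 32 lower (median -0.19, adjusted p = 0.0432), as with Aldoa (-0.25) and Vegfa (-0.48). For each of these 6 lists, adjusted p = 0.909 with an estimated correlation, and with the donor as a random block the count was 0 lists (adjusted p from 0.0753 to 0.613). With bright probe sets only, fatty acid oxidation (0.137), oxidative phosphorylation (0.154) and goblet genes (0.174) lost their calls. Only 5 of the 6 lists kept at least 5 bright genes and were tested in this setting.

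Across all genes limma called 0 of 23099 probe sets for rosiglitazone in the arrays labelled knockout. At an unadjusted p under 0.05 there were 706 without a block (1155 expected), 1560 with the donor as a random block and 1729 as a fixed block. With the donor as a random block limma called 1, a dim second probe set of Zmpste24 chosen after its values were seen (-0.98 without the block, adjusted p = 0.444; 0.046 with it). Adjusted over the list alone, 0 members of the 6 lists passed, with 0 of fatty acid oxidation, 1 of oxidative phosphorylation, 0 of glycolysis, 1 of proliferation, 1 of goblet and 0 of deep crypt genes at an unadjusted p under 0.05. The 10 genes with the smallest p ran from -0.91 (Mir339) to 1.16 (Mrpl22, a mitochondrial ribosomal protein), with Kir3dl1 (0.76), Gse1 (0.63), Tcl1b4 (-0.54), Zcchc10 (-0.58), Smcp (-0.58), Smim38 (-0.61), Kif2b (-0.64) and Wfdc6a (-0.73), all at adjusted p = 1. All but fatty acid oxidation (0.0303, or 0.929 with an estimated correlation) lost their calls on the 4 mice with both treatments (0.571 to 0.807), and goblet and glycolysis genes turned direction. All 6 list calls were lost without knockout-labelled rosiglitazone replicate 2 (adjusted p from 0.114 to 0.828, with goblet and glycolysis genes turning direction) or vehicle replicate 2 (0.0717 to 0.984, with fatty acid oxidation turning). Glycolysis, proliferation, goblet and deep crypt calls ended without vehicle replicate 1 (0.101 to 0.773), and fatty acid oxidation without rosiglitazone replicate 1 (0.362). Glycolysis and goblet calls ended without wild-type rosiglitazone replicate 1 (0.0642 each), and together with fatty acid oxidation without wild-type rosiglitazone replicate 2 (0.0564 each).

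The difference between the responses, knockout-labelled minus wild type, was positive for 3 lists at the preset correlation only (adjusted p = 0.941 each with an estimated correlation) and passed for no single gene. Oxidative phosphorylation had 37 of 46 genes with a positive difference (median 0.11, adjusted p = 0.00105), colonocyte genes 24 of 41 (median 0.10, adjusted p = 0.0294) and goblet cell genes 18 of 27 (median 0.28, adjusted p = 0.0295). With the 4 mice that had both treatments, oxidative phosphorylation (median 0.00, adjusted p = 0.823) and goblet genes (median 0.05, adjusted p = 0.894, direction turned) lost their calls and colonocyte genes kept theirs (0.0448, or 0.92 with an estimated correlation). Centring took the medians of oxidative phosphorylation and colonocyte genes to 0.07 and 0.06, while relative to the median of all probe sets they stayed at 0.14 each. Guca2a differed by 2.52 (SE 0.67) and Slc9a3 by 2.51 (SE 0.69). Slc9a3 read -0.62 and -0.52 for rosiglitazone against vehicle in wild-type mice 42 and 47, and 1.15 and 1.44 in mice 44 and 46 of the arrays labelled knockout. Ndufa4 differed by 0.66 (SE 0.25), and the goblet genes Agr2 and Muc2 by 2.81 (SE 1.69) and 2.18 (SE 1.52), or 1.45 and 0.83 on the mice with both treatments. Pdk4 differed by -1.19 (SE 0.61), Cidec by -0.97 (SE 0.66), Angptl4 by -0.57 (SE 1.05) and Plin2 by -0.37 (SE 0.33), all at adjusted p = 1. On the mice with both treatments these were -1.74, -0.96, -1.95 and -0.57, and over all alternatives Angptl4 ran from -1.95 to 0.11. The PPAR target list was not called (33 of 46 negative, median -0.08, adjusted p = 0.307). Within the 4 mice with both treatments PPAR targets (median -0.11, adjusted p = 0.0112) and fatty acid oxidation (median -0.11, adjusted p = 0.0412) passed as lower, each at adjusted p = 0.92 with an estimated correlation.

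For the difference of responses limma called 0 of 23099 probe sets, with 536 at an unadjusted p under 0.05 and 1155 expected. With the donor as a random or a fixed block there were 1147 and 1175 at that p. Adjusted over the list alone, 0 members of the 3 lists passed, with 1 oxidative phosphorylation, 2 colonocyte and 0 goblet genes at an unadjusted p under 0.05. The 10 genes with the smallest p were Mrpl22 (1.24), Zfp566 (0.84), Slc25a2 (-0.71), Dlx3 (-0.82), Smcp (-0.82), Adhfe1 (-0.86), Plppr1 (-0.88), Zcchc10 (-0.89), Zmynd12 (-1.05) and Wfdc6a (-1.06), each at adjusted p = 1. With the donor as a random block 0 lists passed (adjusted p from 0.0555 to 0.386), and without wild-type rosiglitazone replicate 1 all 3 were lost (0.224 to 0.277) and 4 other lists passed, all lower. The oxidative phosphorylation call also ended without knockout-labelled vehicle replicate 2 (0.0835). The colonocyte call ended without knockout-labelled vehicle replicates 1 (0.0559) or 2 (0.175), knockout-labelled rosiglitazone replicates 1 (0.0777) or 3 (0.0775), wild-type rosiglitazone replicate 2 (0.194) or wild-type vehicle replicate 2 (0.172). The goblet call ended without knockout-labelled rosiglitazone replicate 2 (0.755), knockout-labelled vehicle replicate 1 (0.444), wild-type rosiglitazone replicate 2 (0.062) or wild-type vehicle replicates 1 (0.0605) or 2 (0.0703). Across 18820 genes, which are not independent replicates, the responses of the genotypes correlated at r = -0.084 (Spearman rho -0.066), and at r = 0.037 on the mice with both treatments.

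In vehicle, colonocyte genes were lower as a group in the arrays labelled knockout, with large differences for a few of them. The list was called at the preset correlation only (adjusted p = 0.691 with an estimated correlation). Cyp2c65, a cytochrome P450, differed by -3.92 (SE 0.61, adjusted p = 0.208), Slc9a3 by -3.08 (SE 0.53, adjusted p = 0.363), Cyp2c55 by -2.31 (SE 0.55) and Guca2a by -2.19 (SE 0.52, each at adjusted p = 0.787). The Cyp2c65 readings in the arrays labelled knockout, 2.14 and 1.91, lay below the lower quartile of each array, so its difference is a lower bound. Mt1, a metal-binding metallothionein, differed by 1.77 (SE 0.19, adjusted p = 0.0601). Further genes with the smallest p were Gsdmc2, of the pore-forming gasdermin family (-4.32), Apol10a (-2.51), Ptges, a synthase of prostaglandin E (-1.88), Foxd2, a forkhead transcription factor (-1.44), Wfdc6a (1.06), Cytip (0.88) and Alox5ap, a partner of 5-lipoxygenase (0.88), with adjusted p from 0.0773 to 0.363. For each gene n = 2 and 2.

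The colonocyte list was lower in 31 of 41 genes (median -0.20, adjusted p = 3.71e-05, or 0.691 with an estimated correlation). Of its members 6 fell when adjusted over the list alone, against 0 over all genes. Oxidative phosphorylation was lower in 40 of 46 (median -0.13, adjusted p = 6.94e-05; adjusted p = 0.779 with an estimated correlation), as with Uqcrq (-0.41) and Sdhd (-0.40). Proliferation was lower in 25 of 42 (median -0.05, adjusted p = 0.0142; adjusted p = 0.779 with an estimated correlation), as with Mcm3 (-0.39) and Cdc6 (-0.42). The interferon list was lower in 28 of 41 (median -0.11, adjusted p = 0.0169; adjusted p = 0.779 with an estimated correlation), as with Psmb9 (-0.82) and Zbp1 (-1.27). The enteric nervous system list was higher in 9 of 11 (median 0.21, adjusted p = 0.0239; adjusted p = 0.691 with an estimated correlation), with Nefm, a neurofilament (1.01, SE 0.19), higher when adjusted over the list alone, though its group means were 3.34 and 2.33, near the dim end of the arrays. Centring each array on its median shifted all differences of this comparison by 0.13, which took the medians of oxidative phosphorylation to 0.00, proliferation to 0.08 and interferon to 0.01. Relative to the median of all probe sets the 5 lists lay at -0.23, -0.16, -0.08, -0.14 and 0.17, in the order given, with either scaling.

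Over all genes limma called 0 of 23099 probe sets for genotype in vehicle (1314 at an unadjusted p under 0.05, 1155 expected). Adjusted over the list alone, 0 members of oxidative phosphorylation, proliferation and interferon passed (0, 1 and 4 at an unadjusted p under 0.05). With the donor as a random block 1 gene, Mt1, passed (adjusted p = 0.0213, from 0.00748 to 0.572 over its alternatives) and the proliferation list did not (0.202). Bright probe sets alone ended the calls of proliferation (0.331) and interferon (0.548). In this setting 4 of the 5 lists kept at least 5 bright genes and were tested. Without wild-type rosiglitazone replicate 1, which is in the fit but not in this comparison, 6 probe sets passed (2 higher, 4 lower), among them Mt1 (adjusted p = 0.0364), Apol10a (0.00477), Cyp2c65 (0.00163) and Slc9a3 (0.0201). The list calls of proliferation, interferon and enteric nervous system genes ended without knockout-labelled vehicle replicate 1 (0.12, 0.146 and 0.127, with interferon turning direction). The proliferation call also ended without knockout-labelled vehicle replicate 2 (0.0617) or wild-type vehicle replicate 2 (0.334), and the interferon call without the last of these (0.121). The enteric nervous system call also ended without knockout-labelled vehicle replicate 2 (0.0846) or wild-type vehicle replicate 1 (0.107).

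In rosiglitazone, Mt1 was higher and Cyp2c65, Arl14, Adhfe1 and 1810065E05Rik were lower in the arrays labelled knockout, with no overlap between the 3 arrays of each genotype in any of these genes. Mt1 (probe set 10574027) rose by 2.01 (SE 0.16, adjusted p = 0.00261), or 4.02-fold. Cyp2c65 fell by 4.16 (SE 0.50), Arl14, a small GTPase, fell by 1.56 (SE 0.19, 2.95-fold) and Adhfe1, a mitochondrial alcohol dehydrogenase, fell by 1.05 (SE 0.13, 2.07-fold), each at adjusted p = 0.04. The predicted gene 1810065E05Rik, chosen after its values were seen, fell by 5.57 (SE 0.64, adjusted p = 0.04), to readings of 3.23 to 4.13 near the array medians, so no fold is given. For Cyp2c65 the arrays labelled knockout read 1.75 to 2.04, below the lower quartile of each array, near the background, so its decrease can be read only as a lower bound. Group means in vehicle showed the same order for each of these 5 genes.

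**Figure D3:**
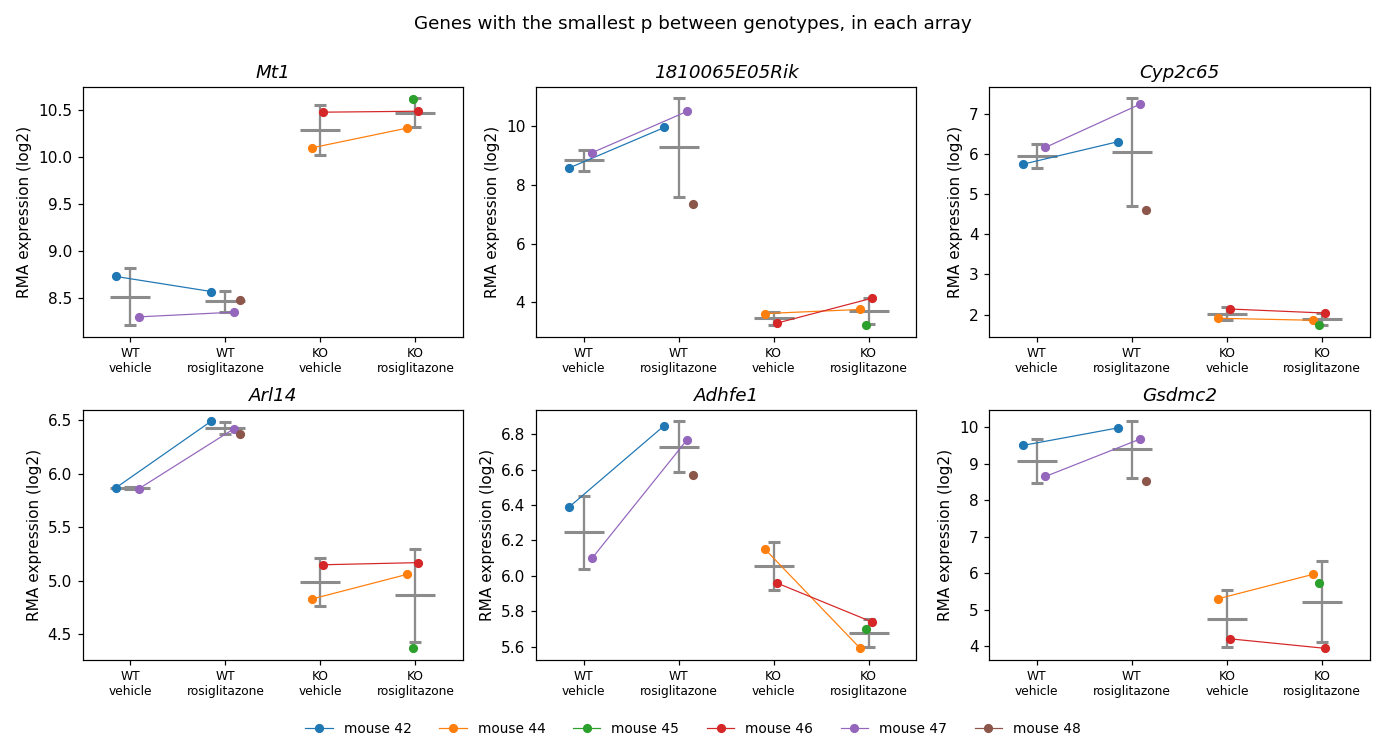
RMA expression (log2) of Mt1, 1810065E05Rik, Cyp2c65, Arl14, Adhfe1 and Gsdmc2 by group, with 1 point per array coloured by mouse, lines joining the arrays of a mouse, and grey bars for the group mean and SD. Mt1 lies at 8.30 to 8.73 in the wild-type arrays and at 10.10 to 10.62 in those labelled knockout.

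Among genes that missed the threshold, the gasdermin genes Gsdmc2, Gsdmcl-ps and Gsdmc differed by -4.18 (SE 0.55, adjusted p = 0.0511), -3.10 (SE 0.44, 0.0772) and -1.08 (SE 0.16, 0.0997), the last a lower bound because Gsdmc read 2.07 to 2.41 in the arrays labelled knockout, near the background. Their sequences are related, so signal shared between their probes cannot be excluded. Krt23, a keratin, differed by 1.16 and Myrfl by 2.05 (adjusted p = 0.0511 each), and Foxd2 by -1.40 (adjusted p = 0.114). Myrfl lay near the background in wild type (mouse means 2.32 to 2.49), so its difference is a lower bound too. Plin2 differed by -0.90 (SE 0.21, adjusted p = 0.526), Cidec by -1.34 (SE 0.42, 0.915), Pdk4 by -1.07 (SE 0.39, 0.962) and Angptl4 by -0.85 (SE 0.66, 0.999), the last 2 moving to -1.62 and -2.23 on the mice with both treatments. Pdk4 was dim in the arrays labelled knockout, so its difference may be compressed.

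The PPAR target list was lower in the arrays labelled knockout in 30 of 46 genes (median -0.10, adjusted p = 0.0192; adjusted p = 0.742 with an estimated correlation), against Lpl, which differed by 0.40. Fatty acid oxidation was lower in 23 of 31 (median -0.12, adjusted p = 0.00954; adjusted p = 0.797 with an estimated correlation), with Cpt2 at -0.46 and Acaa2 at -0.50. Peroxisome genes were lower in 24 of 31 (median -0.13, adjusted p = 0.0119; adjusted p = 0.742 with an estimated correlation), with Acox2 at -0.48 and Pex11a at -0.47. Glycolysis and hypoxia genes were lower in 29 of 32 (median -0.13, adjusted p = 0.00536; adjusted p = 0.797 with an estimated correlation), with Ndrg1 at -1.11. Interferon genes were lower in 30 of 41 (median -0.13, adjusted p = 0.027; adjusted p = 0.866 with an estimated correlation), with Ifit2 at -0.50. Enteroendocrine genes were higher in 23 of 33 (median 0.11, adjusted p = 0.0277; adjusted p = 0.742 with an estimated correlation), with Cpe, a prohormone-processing enzyme, at 1.07 and Gcg, which encodes glucagon peptides, at 0.59. Small intestinal identity genes were higher in 20 of 29 (median 0.09, adjusted p = 0.0192; adjusted p = 0.742 with an estimated correlation). Among them Apob, the apolipoprotein of chylomicrons, was higher by 2.10 (SE 0.40) when adjusted over the list alone, while Rbp2 and Cbr2 differed by -1.09 and -1.18. Centring each array shifted the differences of this comparison by 0.09, which took the medians of PPAR targets, fatty acid oxidation, peroxisome and glycolysis genes to -0.01, -0.03, -0.04 and -0.04. Relative to the median of all probe sets they lay at -0.10, -0.12, -0.13 and -0.13 with either scaling. Adjusted over the list alone, 0 members of the other 6 lists passed, with 6 of fatty acid oxidation, 10 of PPAR targets, 1 of glycolysis, 4 of peroxisome, 2 of enteroendocrine and 1 of interferon genes at an unadjusted p under 0.05.

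Over all genes limma called 5 of 23099 probe sets for genotype in rosiglitazone, 1 higher and 4 lower (1110 at an unadjusted p under 0.05, 1155 expected). Mt1 passed in all 19 alternatives that gave it a value (adjusted p from 0.000213 to 0.032), 1810065E05Rik in 7 of 19 (5.53e-05 to 0.263), Cyp2c65 in 7 of 18 (0.000159 to 0.263), Arl14 in 6 of 19 (0.0124 to 0.267) and Adhfe1 in 6 of 19 (0.0228 to 0.288). With the donor as a random block Gsdmc2 passed as well (adjusted p = 0.0346, from 0.0228 to 0.327 over its alternatives). The count was 23 without wild-type rosiglitazone replicate 1, 3 without knockout-labelled rosiglitazone replicate 2 or wild-type rosiglitazone replicate 3, and 1 without knockout-labelled rosiglitazone replicates 1 or 3, wild-type rosiglitazone replicate 2, or any of the 4 vehicle arrays. On the 4 mice with both treatments it was 16, with Plin2 among them (-1.11, adjusted p = 0.0462, from 0.0174 to 1 over its alternatives). That fit set mice 44 and 46 against 42 and 47 without a block, so the arrays of a mouse counted as independent. All 7 list calls ended without knockout-labelled rosiglitazone replicate 2 (adjusted p from 0.258 to 0.725, with glycolysis turning direction) or wild-type rosiglitazone replicate 3 (0.0543 to 0.877). All but interferon ended without wild-type rosiglitazone replicate 2 (0.0782 to 0.144), and small intestinal identity without knockout-labelled rosiglitazone replicate 3 (0.0601). On the 4 mice with both treatments glycolysis (0.365), enteroendocrine (0.672), interferon (0.164) and small intestinal identity (0.151) lost their calls, while proliferation (0.000204), oxidative phosphorylation (0.00123) and fatty acid synthesis (0.0476) passed as lower (0.456 to 0.654 with an estimated correlation). Bright probe sets alone ended the calls of fatty acid oxidation (0.0573), peroxisome (0.0548), interferon and small intestinal identity (0.185 each). There 6 of the 7 lists kept at least 5 bright genes and were tested.

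The calls of single genes other than Mt1 were lost when single arrays were left out, while the differences stayed close in size. Where the call was lost they ran from -5.79 to -4.96 for 1810065E05Rik, -4.24 to -4.04 for Cyp2c65, -1.71 to -1.53 for Arl14 and -1.08 to -0.99 for Adhfe1. Without wild-type rosiglitazone replicate 2 the adjusted p of 1810065E05Rik, Cyp2c65, Arl14 and Adhfe1 was 0.263 each. Without either knockout-labelled vehicle array it was 0.091 each, and without either wild-type vehicle array 0.09 each. Vehicle arrays are not in this comparison and the differences were unchanged, so these losses came through the spread estimated by the fit. Without knockout-labelled rosiglitazone replicate 1 the adjusted p was 0.0725, 0.0984, 0.0725 and 0.109. Without replicate 3 of that group it was 0.113, 0.147, 0.113 and 0.162. Without replicate 2 of that group 1810065E05Rik, Cyp2c65 and Adhfe1 missed the threshold (0.126 each), while Krt23 passed (0.0127). Without wild-type rosiglitazone replicate 3 the values of 1810065E05Rik, Arl14 and Adhfe1 were 0.0747, 0.267 and 0.288. Without wild-type rosiglitazone replicate 1 Arl14 missed (0.0537), whereas Pdk4 (-1.64, adjusted p = 0.0244), Plin2 (-1.18, 0.0174), Foxd2 (-1.63, 0.0174), Gsdmc2 (-4.61, 0.0296) and Gsdmcl-ps (-3.65, 0.00806) passed.

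Over the 5 comparisons 26 list calls were made, for 13 of the 32 lists, and with an estimated correlation 0 passed (lowest adjusted p = 0.691). The other 19 lists passed in none. Their lowest adjusted p over the 5 comparisons ran from 0.0722, for antimicrobial and mucosal defence, to 0.781, for adipocyte differentiation. Intestinal stem cell genes reached 0.762, colonic identity 0.668, lipid droplet genes 0.105, xenobiotic metabolism 0.679, and markers of immune, mesenchymal and endothelial cells 0.153, 0.175 and 0.175.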

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

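The tests of the 3 patterns weighed here were chosen after the result was seen, except the relabelling of arrays into other groups of 3, which was chosen before. The difference of responses, its random block and its estimated correlation were also chosen before, and the lists on mice with both treatments after.

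Wild-type rosiglitazone replicate 1, the only array of mouse 48, lay near vehicle in PPAR target genes, with a slope over the 46 genes of -0.139 (bootstrap interval over genes, which are not independent, -0.421 to 0.114) where mice 42 and 47 gave 0.888 against each other (0.664 to 0.995). Organoids that received no active rosiglitazone, or a vehicle array under a rosiglitazone label, could give such a slope. A knockout array under a wild-type label, swapped with knockout-labelled rosiglitazone replicate 2, would score above that array over 100 probe sets. The scale was 0 for wild type and 1 for knockout. Wild-type rosiglitazone replicate 1 scored lower, at 0.395 against 0.676 (difference -0.281, interval -0.481 to -0.043 over probe sets that are not independent). The probe sets and the scale were taken from vehicle arrays, and neither mouse of this pair had one. The other wild-type rosiglitazone arrays, at -0.049 and -0.109, came from mice 42 and 47, whose vehicle arrays were used. Their scores thus cannot show whether 0.395 lies between the genotypes. A mouse whose organoids respond less remains open, since 1 array of mouse 48 was measured. Another rosiglitazone array of mouse 48 beside a vehicle array would separate these.

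The genes called between genotypes in rosiglitazone were compared with other causes than the loss of PPARγ. The called genes did not lie in a chromosome segment carried along with the floxed Pparg. Of these genes 0 were among 175 measured neighbours (5.71% at an unadjusted p under 0.05, against 5.03% of all 18820 genes), and 0 were on its chromosome. An effect of such a segment on genes elsewhere was not tested, nor was the Cre insertion site. A lower share of all colonocytes alike, as the whole cause of the lower Cyp2c65, was not borne out. The other 40 colonocyte genes had a median of -0.092 (-0.124 over the 33 bright ones) beside -4.16. A median over the list cannot test the loss of a subset of colonocytes, which stays open. Arrays can be split 3 v 3 in 10 ways, too few for a share under 0.05, and the labelled split, with 5 genes, was the only 1 with as many (highest other 2). For lists 5 of 10 splits had as many as the 7 of the labelled split and the highest other had 15, all at the preset correlation between genes.

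The Pparg probe set was not lower in the arrays labelled knockout. Pparg left working in these organoids would let PPAR targets respond, and the slope of mice 44 and 46 over the PPAR target list was 0.061 (interval -0.059 to 0.232), but wild-type rosiglitazone replicate 1 was as low, so this stays open. Probes outside the floxed exons that still see RNA stay open too, because there was 1 Pparg probe set and its place in the gene was not given in the sources used here. Sequencing reads over exons 1 and 2 would separate these.

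The responses of the genotypes differed by a median of 0.112 over oxidative phosphorylation, 0.104 over colonocyte genes and 0.275 over goblet cell genes, each tested as an interaction, and all 3 calls were lost with the donor as a random block and with an estimated correlation (adjusted p = 0.941 each). On the 4 mice with both treatments the medians were -0.004, 0.128 and 0.047.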

How the results depend on the processing

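Counts of probe sets and lists depended on the settings, and the cause was not tested unless given. At an unadjusted p under 0.01 the counts were 34 for rosiglitazone in wild type, 106 for rosiglitazone in knockout, 56 for the difference of responses, 263 for genotype in vehicle and 246 for genotype in rosiglitazone. For genotype in vehicle 2 probe sets passed after centring (1 higher, 1 lower), 1 after repeated quantile normalization (higher), 1 with bright probe sets only, 4 with only the groups compared, 2 with an intensity trend and 6 on mice with both treatments. For genotype in rosiglitazone the count of 5 (1 higher, 4 lower) became 7 after centring (2 higher, 5 lower), 1 after repeated quantile normalization (higher) or with only the groups compared, 8 with an intensity trend, 12 with array weights, 16 on mice with both treatments and 1 over all probe sets, the last chosen after seeing the data. The donor as a random block gave 1 for rosiglitazone in knockout and 1 for genotype in vehicle, and Pparg in vehicle at -0.11. Other calls that the block changed are given with their results, and it changed no other call. As a fixed block, limma called 0 in both responses and in their difference (smallest adjusted p 0.257, 0.64 and 0.502). Leaving out 1 array gave 0 to 6 probe sets for genotype in vehicle, 1 to 23 for genotype in rosiglitazone and -0.046 to 0.656 for Pparg in rosiglitazone, which was 0.837 on mice with both treatments. Lists passing fell to 0 in each of the 5 comparisons with an estimated correlation. With bright probe sets only they numbered 8 for wild type, 3 for knockout, 3 for genotype in vehicle and 2 for genotype in rosiglitazone. Lists with fewer than 5 bright genes were not tested in that setting. The random block left 0 in knockout and 0 in the difference. Chosen after seeing the data, the mice with both treatments left 1 list in knockout, and looser symbol matching 3. Leaving out 1 array gave 1 to 6 lists in wild type, 0 to 9 in knockout, 1 to 6 in the difference, 3 to 6 for genotype in vehicle and 0 to 12 for genotype in rosiglitazone. The correlation of responses, -0.084, was 0.037 on mice with both treatments and ran from -0.128 to 0.002 with 1 array left out, positive only without wild-type rosiglitazone replicate 1. Array signal includes background, so differences of dim genes are compressed.

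Of 182 gene results over 3481 alternatives, 3350 kept their direction and stayed on the same side of the threshold, whatever their size, 45 changed sign without a call, 37 gained a call and 49 lost theirs.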

Other observations

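The tests given here were chosen only after the results were seen.

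Beside Muc2 and Defa24, the array of mouse 45 read 8.85 for Agr2, a disulfide isomerase needed for mucin, 8.90 for Zg16, a lectin of mucus, 7.01 for Retnlb and 5.68 for Lyz1, the lysozyme of Paneth cells, each the highest of the 10 arrays. Tff1, a goblet cell peptide, read 3.44 there, as in replicate 1 of its group. With a single mean per mouse, an alternative chosen after seeing the data, limma called 3 of 23099 probe sets between 3 mice of each genotype (832 at an unadjusted p under 0.05). These were Mt1, higher by 1.95 (SE 0.15, adjusted p = 0.00732), Myrfl, higher by 1.86 (SE 0.13, adjusted p = 0.006), and 1810065E05Rik at -5.27 (SE 0.53, adjusted p = 0.0479), and the highest other split had 1. Myrfl lay near the background in wild type, so its difference is a lower bound. In this fit Cyp2c65 (-3.87, adjusted p = 0.0748), Arl14 (-1.41, 0.146) and Adhfe1 (-0.73, 0.258), called between the genotypes in rosiglitazone, missed the threshold.

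Mt1 is a hypothesis for a further test. Metal or stress that induces the metallothioneins together would raise Mt2 with Mt1. In rosiglitazone Mt2 differed by 0.22 (SE 0.56, interval -1.03 to 1.47) beside 2.01 for Mt1. The interval pools the spread of all groups without a block, and Mt2 read 7.12 to 9.72 in knockout-labelled rosiglitazone arrays. These values argue against a joint rise of that size but do not exclude it. A change confined to Mt1, in its locus or in its probes, may remain, and quantitative PCR of Mt1 and Mt2 in further mice would test it.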
